A study of Mus musculus with 2 samples.

How the data were processed

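RNA was measured in Gr-1+ CD11b+ cells of BALB/c mice in 2 libraries, 1 from cells stimulated without ATPγS and 1 from cells stimulated with it. Per the labels' protocols, full-length cDNA was made with the SMART-Seq HT kit and libraries with the Nextera kit, a preparation that does not mark the strand of a transcript. Per the submitters' processing notes, the tools were TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1, with the mouse build mm10. The deposited values are FPKM, fragments per unit of transcript length and of mapped fragments, with 1 value per gene symbol. The gene annotation and the options of each tool are not given in the sources used here.

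Both deposited tables held the same 24346 symbols, none of them repeated, so keeping the largest row of a repeated symbol moved nothing and that alternative is void. FPKM are not read counts, and no count test was run. An exact 0 can be a failed estimate, so such a gene is described as listed at 0 and no fold is given for it. The depth was read from the smallest steps of FPKM times coding length in 1072 olfactory and vomeronasal receptor genes, most of which have 1 coding exon. By this reading the library totals were 2134000 fragments in the control and 2849000 in the ATPγS library, a ratio of 1.33. Of the values under 10 reads, 71.4% in the control and 71.9% in the ATPγS library came out whole within 0.05 reads, where chance gives 10%. Reads per gene were then estimated from transcript lengths of GENCODE M21 (GRCm38, the same build as mm10), and are approximate because the authors' gene models may have had other lengths. Of the symbols, 23310 (95.7%) were found there, which also gave the positions.

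The log2 ratio of each gene was log2((ATPγS FPKM + 1) / (control FPKM + 1)), which understates the difference of low genes. Genes with a mean FPKM of at least 1 over both libraries entered the counts (18311 genes), and a ratio of at least 2-fold on this scale was counted. Folds printed with a gene are ratios of its FPKM without the pseudocount. Higher and lower describe the listed values, and the counting intervals of some genes so described include no difference. With 1 library per group there is no replicate error, so no p-value was computed. Intervals of a ratio or a share are 95% exact binomial (Clopper-Pearson) and cover counting error only, since PCR duplicates cannot be told from independent molecules in these values.

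A set of 37 gene lists was written from the series title, the treatment, the cell type and the other cells the gate could hold. For each of the 34 lists with at least 5 members at a mean FPKM of at least 1, the median log2 ratio was placed among the medians of 10000 random lists of the same size. These were matched on mean expression in 10 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5, which chance gives to 1.7 of 34 lists. Such a percentile describes these 2 libraries and not the conditions.

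The genes named were chosen by a rule in 4 parts. The first took the 12 highest and 12 lowest log2 ratios at a mean FPKM of at least 5, without genes whose symbol marks a small RNA. Short RNA genes under other symbols, such as Gm12238 and Rprl3, were kept. The next took up to 4 members of each list with the largest absolute log2 ratio. Another took every member at a mean FPKM of at least 1 of both glycolysis lists, of the nucleotide and adenosine receptors and of the ectonucleotidases. The last took the 2 most abundant members of each marker list of other cell types. The rule named 223 genes, and the text says where a gene was chosen after its values were seen. The results of some of them are not reported here. The lists, the rule, the thresholds and the first set of alternatives were fixed before the data were examined.

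The alternatives were pseudocounts of 0.1 and 5, rescaling to the same sum or to a median log2 ratio of 0 at a mean FPKM of at least 10, no filter or a mean FPKM of at least 5, small RNA genes left out, thresholds of 1.5-fold and 3-fold, means in place of medians, unmatched random lists and shared members left out. A mean FPKM of at least 20, rescaling to a median of 0 together with a mean FPKM of at least 5 or 20, and random lists matched also on transcript length or GC content, each in 5 bins, were added after seeing the data. The rescalings shifted the median log2 ratio of genes with a mean FPKM of at least 10 by 0.05 (same sum) and 0.13 (median 0), and low genes by less because of the pseudocount, so a ratio closer to 0 than this has no direction.

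The steps were tested on simulated data with counting error only. All 200 genes given a 2.83-fold difference, drawn only at a mean FPKM of at least 20, were recovered (100%). Of 17264 unchanged genes, 354 (2.05%) passed 2-fold at a mean FPKM of at least 1. In the data, 44.3% of 1013 olfactory and vomeronasal receptor genes passed 2-fold at that minimum, so 2.05% is not an error rate for these libraries. Of 300 null lists of 20 genes 2.67% stood apart. All 100 of 100 lists shifted by 0.5 on the log2 scale did, with members drawn at a mean FPKM of at least 5. Both shares of lists hold for counting error only. In the data, the upper limit a median had to pass depended on the list. It was 0.02 for oxidative phosphorylation, 0.46 for the nucleotide and adenosine receptors and 0.48 for the ectonucleotidases. The 100 of 100 is therefore not a recovery rate for these libraries. Near-identical copies of the 24 genes of the first part of the rule were searched with blastn 2.17.0 among GENCODE M21 transcripts (at least 95% identity over at least 50% of the length). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.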

Results

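Gene expression was measured by RNA sequencing in Gr-1+ CD11b+ cells, a sorted myeloid population in which neutrophils and monocytes carry both surface markers. The cells came from BALB/c mice that had received 3% dextran sulfate sodium (DSS), a polymer that induces colitis, for 6 days. One library was made from cells kept for 2.5 hours without ATPγS (control, n = 1) and another from cells given ATPγS, a slowly hydrolysed analogue of ATP that activates nucleotide receptors (n = 1). The label gives its concentration as 100 with the prefix of the molar unit lost. The difference between the libraries has no replicate check, so each value below describes 1 library per condition. The recovered depth was 2134000 fragments for the control and 2849000 for the ATPγS library. Genes listed above 0 numbered 20485 in the control and 21282 in the ATPγS library, with median FPKM of 3.03 and 3.46.

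The series title names a P2X4-dependent metabolism in myeloid cells, and the comparison asks which metabolic, purinergic and inflammatory transcripts differed with ATPγS. Among the most abundant transcripts, Ccl4, a chemokine that attracts macrophages and lymphocytes, was 2.10-fold higher in the ATPγS library (1818 and 3818 FPKM in control and ATPγS). Gapdh and Pkm, enzymes of the lower part of glycolysis, were 1.57-fold and 1.35-fold higher, while Pgam1 of the same part of the pathway was 1.47-fold lower and the glycolytic list did not stand apart from random lists. P2rx4, the gene of the P2X4 receptor, an ATP-gated cation channel, was 2.66-fold higher (9.96 and 26.5 FPKM). Lower in the ATPγS library were Cd3g, a subunit of the T cell receptor complex (76.5 and 19.4 FPKM), Idh3a, a subunit of the NAD-dependent isocitrate dehydrogenase of the TCA cycle (29.7 and 9.64 FPKM), and the interferon-induced chemokine gene Cxcl10 (168 and 82.8 FPKM).

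Of 18 glycolytic enzyme genes, 2 were at least 2-fold higher in the ATPγS library, 0 were at least 2-fold lower and 16 lay between. The 2 were Pfkm, a phosphofructokinase (1.52 and 4.57 FPKM), and Ldhb, a lactate dehydrogenase (6.00 and 13.2 FPKM), both at low levels. Gapdh (chromosome 6, 125161715 to 125166467, GRCm38) stood at 697 and 1091 FPKM, with a counting interval of its ratio of 1.48 to 1.65. Pkm, pyruvate kinase, stood at 578 and 781 FPKM, and the hexokinase gene Hk3 at 45.8 and 67.7 FPKM. Pgam1, phosphoglycerate mutase, was lower in the ATPγS library (194 and 133 FPKM), and Aldoa, aldolase, stood at 839 and 763 FPKM. The other members ranged from Hk1 (log2 ratio 0.46) to Eno2 (log2 ratio -0.33), with Ldha, the main lactate dehydrogenase, at 463 and 508 FPKM, and Hk2, Gpi1, Pfkl, Pgk1 and Eno1 within 0.14 of 0. Pfkp was lower (log2 ratio -0.29), and Tpi1 (0.24) and Aldoc (0.28) were higher. The counting interval of Aldoc (0.62 to 3.15) includes no difference. The median log2 ratio of the list was 0.13, at percentile 94.3 of random lists, so it did not stand apart.

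Among 14 genes of glucose and lactate transport and glycolysis regulation, 3 were at least 2-fold higher in the ATPγS library and 0 at least 2-fold lower. These were Pdk3 (1.22 and 11.98 FPKM) and Pdk1 (1.24 and 5.12 FPKM), kinases that inhibit pyruvate dehydrogenase, and the monocarboxylate transporter gene Slc16a1 (4.72 and 11.5 FPKM). The more abundant transporters differed less, with the glucose transporter gene Slc2a1 at 63.1 and 81.9 FPKM and the lactate exporter gene Slc16a3 at 196 and 239 FPKM. Slc2a3, Slc2a6, Pfkfb3 and Pdk4 lay within 0.13 of 0. Pdk2 (log2 ratio 0.95), Tigar (0.30) and Pfkfb4 (0.23) were higher, and Pfkfb1 (-0.76) and Pfkfb2 (-0.91) were lower. The counting intervals of Tigar (0.52 to 4.12), Pfkfb4 (0.95 to 1.49) and Pfkfb1 (0.092 to 1.68) include no difference. The list had a median of 0.26 at percentile 93.0 and did not stand apart.

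The mitochondrial lists lay on the lower side, where genes with a mean FPKM of at least 10 as a whole had a median log2 ratio of -0.13. Of 20 TCA cycle genes, 16 had a log2 ratio below 0 (15 after rescaling to a median of 0), and Idh3a was the 1 member at least 2-fold lower (chromosome 9, 54586334 to 54604661). Suclg1, a subunit of succinyl-CoA ligase, stood at 30.4 and 16.8 FPKM, and Ogdh, of the oxoglutarate dehydrogenase complex, was higher at 15.4 and 28.7 FPKM. The median was -0.29 at percentile 11.4. Of 56 nuclear-encoded genes of oxidative phosphorylation, 41 lay below 0 (35 after rescaling), and the respiratory chain genes Uqcrc2 (38.8 and 16.4 FPKM) and Ndufs4 (30.7 and 13.3 FPKM) were the 2 at least 2-fold lower. The ATP synthase gene Atp5j stood at 258 and 142 FPKM, and the list's median was -0.19 at percentile 13.4. In the pentose phosphate pathway, 1 of 6 genes was at least 2-fold lower, Rpe (16.8 and 6.50 FPKM), and G6pdx, of its first enzyme, stood at 131 and 81.7 FPKM (list median -0.22, percentile 32.4). None of these 3 lists stood apart, and the list of mitochondrially encoded genes had 0 members in the tables.

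The nucleotide and adenosine receptor list had 15 measured members, of which 2 were at least 2-fold higher in the ATPγS library and 0 at least 2-fold lower. P2rx4 (chromosome 5, 122707544 to 122729738) had a counting interval of its ratio of 1.86 to 3.88, from about 40 and 142 reads, and lay at percentile 97.9 of the 501 genes nearest in mean FPKM. That interval covers counting error only, and the olfactory and vomeronasal receptor genes used as background below spread more widely than counting error. P2ry6, of the UDP receptor, stood at 4.89 and 13.04 FPKM. P2ry2, of a receptor for ATP and UTP and the most abundant of the list, stood at 64.2 and 72.5 FPKM. P2ry13, of an ADP receptor, was lower (24.4 and 14.1 FPKM). P2ry10, not an established nucleotide receptor despite its symbol, was lower too (29.9 and 22.9 FPKM). The adenosine receptor genes Adora3 (5.03 and 10.4 FPKM), Adora1 (3.32 and 6.59 FPKM) and Adora2b (12.4 and 17.6 FPKM) were higher, and P2rx7, of another ATP-gated channel, stood at only 2.37 and 3.31 FPKM. P2ry12 (log2 ratio 0.53), P2ry14 (0.30) and P2ry1 (0.16) were higher, and P2rx1, P2ry4 and Adora2a lay within 0.10 of 0. Counting error alone can give the direction of some of these genes. The counting intervals of P2ry12 (0.59 to 6.51), P2ry14 (0.93 to 1.68), P2ry1 (0.55 to 2.87) and Adora2b (0.995 to 2.05) include no difference. The median was 0.30 at percentile 91.6, so the list did not stand apart.

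The ectonucleotidase list, of enzymes that break down nucleotides or nucleosides, not all of them at the cell surface, and the ATP release channel gene Panx1, did stand apart, with a median of 0.52 over 15 members at percentile 98.3. At least 2-fold higher in the ATPγS library were 3 members, Entpd5 (0.233 and 7.92 FPKM), Enpp4 (1.17 and 5.67 FPKM) and Entpd8 (chromosome 2, 25080304 to 25085716), the gene of the enzyme in the series title, which was listed at 0 in the control and at 2.2 FPKM with ATPγS. All 3 have a mean FPKM of 1 to 5. At that level 1781 of all 8419 genes were at least 2-fold higher and 921 at least 2-fold lower. Entpd1, of the ectonucleotidase CD39, was by far the most abundant and hardly differed (141 and 139 FPKM). Nt5e, of the AMP-degrading enzyme CD73, stood at 9.46 and 13.9 FPKM and Entpd2 at 11.5 and 17.8 FPKM. Entpd6 (log2 ratio 0.75), Entpd7 (0.57), Enpp3 (0.57), Enpp1 (0.52), Alpl (0.22) and Entpd3 (0.20) were higher, Enpp2 was lower (-0.16), and Ada and Panx1 lay within 0.08 of 0. The counting intervals of Entpd6 (0.88 to 5.35), Alpl (0.83 to 1.68), Entpd3 (0.84 to 1.66) and Enpp2 (0.64 to 1.24) include no difference. Only 1 of the 15 members reached a mean FPKM of 20, and the list no longer stood apart among genes with a mean FPKM of at least 5 (median 0.21, percentile 86.9) or against random lists matched on GC content (0.52, percentile 97.4).

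**Figure D1:**
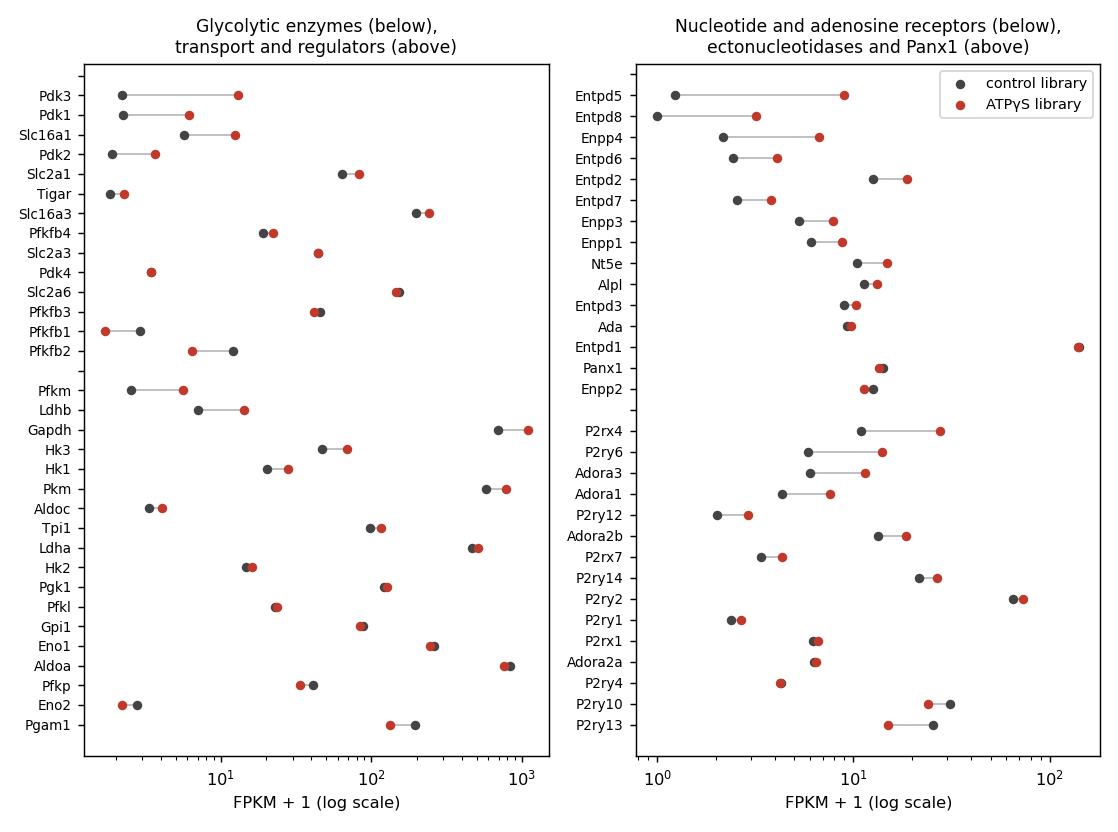
FPKM + 1 on a log axis of each measured member of the glycolysis lists (left) and of the receptor and ectonucleotidase lists (right), with 1 point for the control library (grey) and 1 for the ATPγS library (red). Gapdh (697 and 1091 FPKM) and P2rx4 (9.96 and 26.5 FPKM) lie to the right in the ATPγS library, while the points of Entpd1 (141 and 139 FPKM) overlap.

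Immediate early genes, which respond quickly to stimulation, stood apart with a median of 0.16 over 30 members at percentile 99.4, although 0 members reached a 2-fold difference in either direction. Atf3, a stress-induced transcription factor gene (166 and 306 FPKM), Nr4a3 (23.3 and 43.3 FPKM), an orphan nuclear receptor gene, and Nr4a2 (12.6 and 22.8 FPKM), of the same family, were higher in the ATPγS library. Srf, of a regulator of such genes (7.37 and 3.21 FPKM), and Dusp6, of a phosphatase of ERK (36.1 and 20.1 FPKM), were lower. Fos (410 and 367 FPKM) and Egr1 (423 and 356 FPKM), chosen after their values were seen, were slightly lower. Genes with a mean FPKM of at least 10 as a whole had a median log2 ratio of -0.13. The list did not stand apart by its mean (0.14, percentile 84.7), against unmatched lists (0.16, percentile 82.6) or against lists matched on GC content (0.16, percentile 96.3).

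Few genes of inflammatory mediators reached a 2-fold difference. Of 20 chemokine genes, 2 were at least 2-fold higher in the ATPγS library, Ccl4 (chromosome 11, 83662584 to 83664683) and Ccl17 (1.21 and 8.14 FPKM), and 1, Cxcl10, was at least 2-fold lower. The neutrophil attractant gene Cxcl5 stood at 69.2 and 40.8 FPKM, and the list's median was -0.06 and its mean 0.03 (percentile 59.4). None of 21 cytokine genes reached 2-fold. Csf3, of the granulocyte growth factor G-CSF (26.1 and 45.7 FPKM), and Vegfa, of an angiogenic factor (10.5 and 16.8 FPKM), were higher, and Il18 (11.1 and 5.82 FPKM) and Il12b (16.1 and 9.34 FPKM) were lower, with a list median of 0.09 (percentile 93.2). The counting interval of Il18 (0.25 to 1.09) includes no difference. In the NF-κB list, 1 of 22 genes was at least 2-fold higher, Nos2, of inducible nitric oxide synthase (0.862 and 6.53 FPKM), while the prostaglandin synthase gene Ptgs2 stood at 114 and 194 FPKM and the NF-κB inhibitor gene Nfkbia at 2168 and 2795 FPKM (median 0.08, percentile 95.3). Of 30 interferon-stimulated genes, Cmpk2 was the 1 at least 2-fold lower (61.5 and 27.7 FPKM), Zbp1, of a nucleic acid sensor, stood at 71.7 and 42.1 FPKM, and Oas1a was higher at 7.56 and 14.7 FPKM (median -0.20, percentile 16.7). Neither these 4 lists nor those of the next paragraph stood apart.

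Among 20 cAMP-responsive genes, 2 were at least 2-fold higher in the ATPγS library, the clock gene Per1 (0.979 and 5.50 FPKM) and the phosphodiesterase gene Pde4a (0.326 and 2.62 FPKM), with a median of 0.04 (percentile 75.8). Hypoxia targets outside glycolysis split, with Egln1 (1.53 and 9.32 FPKM), Ddit4 (0.984 and 4.05 FPKM) and P4ha2 (1.58 and 4.32 FPKM) at least 2-fold higher and Egln3, of another prolyl hydroxylase of the same family as Egln1, at least 2-fold lower (27.9 and 7.37 FPKM). The median of these 19 genes was -0.19 and their mean 0.04 (percentile 25.7). None of the 15 NRF2 and oxidative stress genes reached 2-fold. The glutathione synthesis gene Gclc stood at 33.0 and 53.7 FPKM and the thioredoxin gene Txn1 at 376 and 277 FPKM (median 0.04, percentile 87.3). The 6 genes of the NADPH oxidase had a median of -0.15 (percentile 38.9), with Cyba at 806 and 576 FPKM. The 10 inflammasome genes had a median of -0.03 and a mean of 0.04 (percentile 56.2), with Mefv, of the sensor pyrin, at 107 and 154 FPKM and Nek7 at 25.6 and 15.8 FPKM. In the list of kinases and effectors downstream of growth factor and nucleotide receptors, 0 of 14 genes reached 2-fold. Mtor (2.94 and 1.034 FPKM), Ppp3ca, of calcineurin (20.2 and 10.1 FPKM), and Mapk14, of the p38 kinase (34.6 and 21.1 FPKM), were lower and Nfatc1 was higher (29.3 and 47.7 FPKM), with a median of -0.18 (percentile 29.1).

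Neutrophil transcripts were abundant in both libraries. S100a8 and S100a9, chosen after their values were seen, encode the calprotectin subunits and stood at 20604 and 13776 FPKM in the control and at 22409.6 and 14942 FPKM in the ATPγS library. Of 19 neutrophil markers, 1 was at least 2-fold higher, the chemokine receptor gene Cxcr1 (0.398 and 8.63 FPKM). The histidine decarboxylase gene Hdc was higher (512 and 771 FPKM) and the formyl peptide receptor gene Fpr1 lower (897 and 626 FPKM), with a list median of 0.05 (percentile 91.4). Neutrophil activation and ageing genes had a median of 0.02 and a mean of -0.00251 over 18 members (percentile 85.9), with Tlr4, of the endotoxin receptor, at 37.4 and 26.6 FPKM. Of 12 secondary and tertiary granule genes, 1 was at least 2-fold higher, the cathelicidin gene Camp (12.2 and 28.9 FPKM), with a median of 0.07 (percentile 90.3). The primary granule list had only 3 measured members and was not tested, with the cathepsin G gene Ctsg at 0.459 and 2.41 FPKM and Serpinb1a at 36.9 and 20.2 FPKM.

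Both lymphocyte marker lists had medians below those of matched random lists, with members on either side of 0. Of 18 T and NK cell markers, 6 were at least 2-fold lower and 2 at least 2-fold higher, and the median of -0.44 stood apart at percentile 1.47. The lower ones were Cd3g (chromosome 9, 44969572 to 44980431), Cd3d of the same complex (31.8 and 9.46 FPKM), the cytotoxic granule genes Nkg7 (22.4 and 2.71 FPKM) and Prf1 (2.75 and 0.147 FPKM) and, chosen after their values were seen, the T cell kinase gene Lck (64.9 and 20.4 FPKM) and the NK receptor gene Ncr1 (13.9 and 6.07 FPKM). The higher ones, chosen in the same way, were Klrb1c (0.750 and 2.70 FPKM) and Tbx21 (0.928 and 3.36 FPKM), and the granzyme gene Gzma was also higher (45.8 and 66.1 FPKM). The 10 B cell markers stood apart as well, with a median of -0.58 at percentile 0.570, with Blk at least 2-fold lower (11.5 and 5.03 FPKM) and Cd22 at least 2-fold higher (1.73 and 6.00 FPKM). Ms4a1, of CD20 (46.1 and 23.7 FPKM), Fcrla (16.4 and 7.88 FPKM), the B cell receptor gene Cd79a (133 and 85.9 FPKM) and the antibody joining chain gene Jchain (929.9 and 643 FPKM) were lower. Cd79b (83.1 and 84.2 FPKM), chosen after its values were seen, hardly differed. With a pseudocount of 5 the T and NK list no longer stood apart (-0.23, percentile 6.50), and by its mean the B cell list did not (-0.40, percentile 9.01).

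No list of the other cell types stood apart. Macrophage and dendritic cell markers had a median of 0.19 over 20 genes (percentile 95.45), which stood apart at a mean FPKM of at least 5 (0.24, percentile 98.2). The complement gene C1qc (12.5 and 34.2 FPKM) and the cytokine receptor gene Flt3 (0.946 and 3.78 FPKM) were at least 2-fold higher in the ATPγS library, Clec9a was at least 2-fold lower (4.82 and 0.198 FPKM), and C1qb stood at 39.7 and 78.9 FPKM. The most abundant members, the antigen presentation gene Cd74 (2647 and 2825 FPKM) and the lipid carrier gene Apoe (611 and 716 FPKM), differed little. Monocyte markers had a median of -0.05 over 15 genes (percentile 52.9), with Ccr2 at 14.7 and 8.82 FPKM, Ms4a6c at 146 and 141 FPKM and Nr4a1 at 315 and 364 FPKM. Of 14 eosinophil, basophil and mast cell markers, 4 were at least 2-fold lower, the IgE receptor gene Fcer1a (12.5 and 2.67 FPKM), the basophil protease gene Mcpt8 (12.2 and 3.04 FPKM), Mcpt4 (2.80 and 0.698 FPKM) and Il5ra (13.975 and 6.41 FPKM). Mcpt4 rests on about 7 and 2 reads, with a counting interval of 0.022 to 1.12 that includes no difference. The median of the 14 markers was -0.28 (percentile 13.5), and the abundant members Ccr3 (41.5 and 30.4 FPKM) and Kit (27.8 and 13.999 FPKM) were lower too. Of 7 erythroid and platelet genes, the platelet genes Pf4 (13.6 and 52.9 FPKM) and Itga2b (1.57 and 6.64 FPKM) and the heme synthesis gene Alas2 (7.36 and 17.9 FPKM) were at least 2-fold higher, whereas the globin genes Hba-a1 (725 and 616 FPKM) and Hbb-b1 (426 and 311 FPKM) were lower, so that the median was -0.06 and the mean 0.52 (percentile 55.8). Epithelial and stromal markers had a median of -0.04 and a mean of 0.08 over 17 genes (percentile 58.1). Of these, 8 had a log2 ratio above 0 and 9 below. The matrix genes Dcn (605 and 587 FPKM) and Col3a1 (227 and 241 FPKM) were abundant in both libraries. Vil1 (listed at 0 in the control, 3.92 FPKM with ATPγS) and Muc2 (0.222 and 2.04 FPKM) were at least 2-fold higher on the log2 scale used. Muc2 rests on about 0 and 4 reads, and its counting interval includes no difference. The more abundant epithelial genes Krt19 (50.8 and 31.3 FPKM) and Cdh1 (10.3 and 5.74 FPKM) were lower.

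The remaining lists did not stand apart either. The 42 cytosolic ribosomal protein genes had a median of -0.15 (percentile 26.7) with 32 members below 0 (21 after rescaling to a median of 0), and Rpl15 stood at 116 and 84.6 FPKM. The 14 housekeeping genes had a median of -0.14 (percentile 41.8), with Ywhaz at 239 and 176 FPKM. Heat shock and unfolded protein genes had a median of -0.03 and a mean of 0.08 over 20 genes (percentile 74.1), and Trib3, a stress-induced pseudokinase gene, was the 1 at least 2-fold higher (0.197 and 8.84 FPKM) while Hsp90aa1 was lower (145 and 89.5 FPKM). Of 15 amino acid transport and mTORC1-linked genes, Rheb, of the GTPase that activates mTORC1, was the 1 at least 2-fold lower (74.7 and 30.7 FPKM; list median -0.09, percentile 51.7). Of 15 cholesterol and fatty acid synthesis genes, the squalene epoxidase gene Sqle was the 1 at least 2-fold lower (11.3 and 4.81 FPKM), and the list median was -0.18 (percentile 33.0). Among 16 proliferation genes, Ccna2 (1.39 and 8.45 FPKM), Cdk1 (0.957 and 3.28 FPKM) and, chosen after its values were seen, Aurkb (1.66 and 4.50 FPKM) were at least 2-fold higher, and Ccnb2 (11.2 and 3.47 FPKM) and Top2a (7.81 and 2.81 FPKM) at least 2-fold lower, with a median of 0.10 (percentile 77.1). The sex-linked list had 4 measured members and was not tested. Its Y-linked gene Eif2s3y was present in both libraries (45.3 and 36.2 FPKM). Of the 37 lists, 34 were tested and 4 stood apart, where chance gives 1.7.

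**Figure D2:**
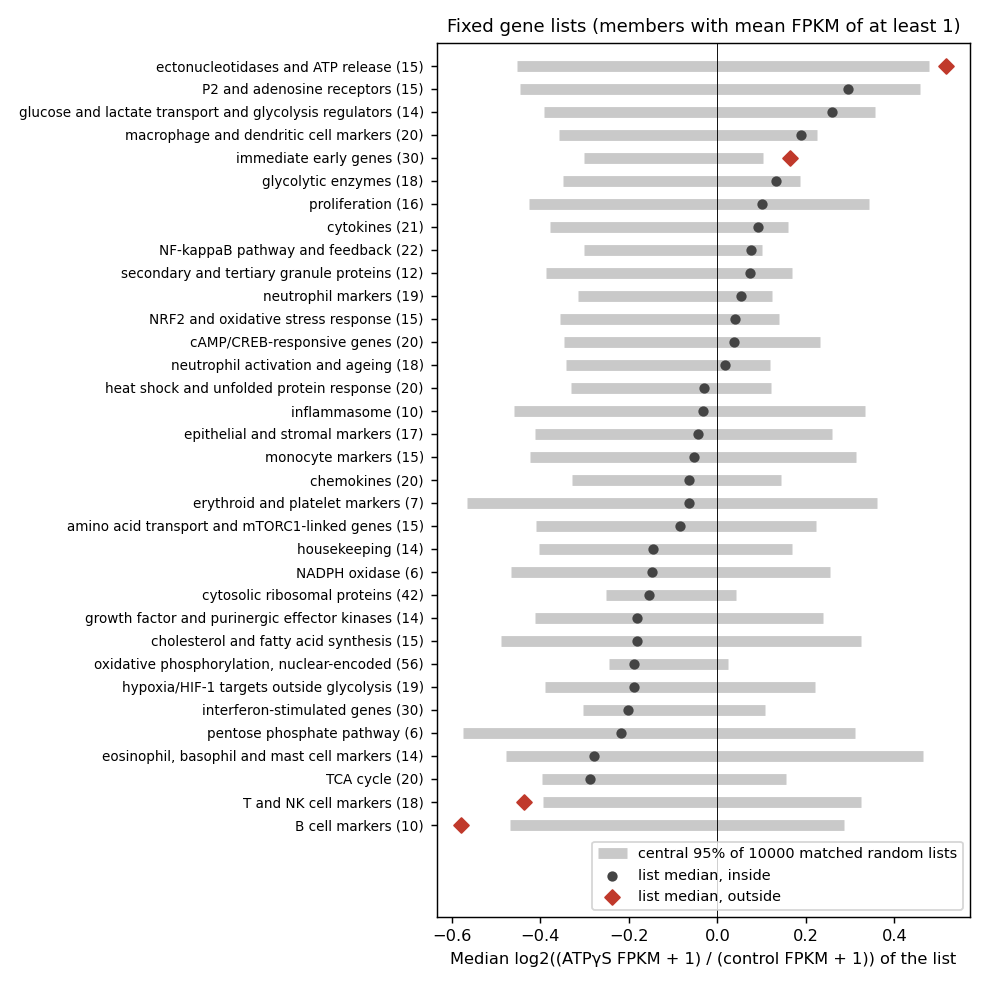
Median log2((ATPγS FPKM + 1) / (control FPKM + 1)) of each of the 34 tested lists, with the number of measured members in parentheses. Grey bars span the central 95% of 10000 random lists matched on expression, and red diamonds mark the 4 medians outside them, from 0.52 for the ectonucleotidases to -0.58 for the B cell markers.

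Over all 18311 genes with a mean FPKM of at least 1, 2521 were at least 2-fold higher in the ATPγS library and 1815 at least 2-fold lower. Which group was larger depended on the minimum and on the scaling. At a mean FPKM of at least 5 the counts were 740 and 894 of 9892 genes, and at a mean of at least 20, a minimum added after seeing the data, 80 and 174 of 3480 genes. With the libraries also rescaled to a median log2 ratio of 0, an alternative chosen after seeing the data, they were 916 and 689 at the first minimum and 110 and 116 at the other. Olfactory receptor genes, which belong to the nose and serve here as a measure of background, were listed above 0 for 76.3% of 1120 genes in the control and for 85.4% in the ATPγS library, and 95% of them lay below 16.5 and 16.7 FPKM. With the vomeronasal receptor genes they differed by at least 2-fold in 49.6% of 629 genes at a mean FPKM of 1 to 5 (interval 45.6 to 53.6), against 30.7% of the 7790 other genes. These sets were matched on FPKM and not on reads, which are fewer in shorter genes at the same FPKM. Members named above with both values below 16.5 FPKM, such as Pdk3, Entpd5, Entpd8, Nos2 and Ccl17, lie within this range of background, as does the control value of P2rx4. Across genes with a mean FPKM of at least 1 the log2 values of both libraries had a Pearson correlation of 0.84, where genes are not independent replicates.

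The most extreme ratios at a mean FPKM of at least 5 belonged mostly to low, short or multi-copy genes. The highest were Gm12238, an RNA gene inside an intron (541.8 FPKM with ATPγS), the defensin genes Defa4 (56.4) and Defb11 (17.2), the seminal vesicle gene Svs4 (39.8), Rprl3 (26.7), Pla2g10os (25.2), Gstp2 (24.7), Cypt2 (18.03), Apoo-ps (17.9), the olfactory receptor gene Olfr750 (17.4) and the lens crystallin gene Crygs (17.0), all listed at 0 in the control. Ccl21a, of a lymphoid chemokine, stood at 0.0950 and 51.8 FPKM. Among the lowest, Cd5, a T cell surface gene, stood at 21.8 FPKM in the control and was listed at 0 with ATPγS, as were Fxyd4 (19.3), Cypt7 (16.1), Defb8 (14.002) and Gm38509 (10.1). The polyamine synthesis gene Amd1 (43.6 and 0.147 FPKM), Gm1987 (56.7 and 0.783 FPKM), the class Ib histocompatibility gene H2-Q6 (70.8 and 2.82 FPKM), Gm5643 (31.6 and 1.07 FPKM), the NK receptor gene Klrd1 (23.3 and 1.25 FPKM), Olfr1043 (15.8 and 0.371 FPKM) and Akr1b3 (14.9 and 0.00200 FPKM) were also among them. Amd1, Gstp2, Apoo-ps, Gm5643, Ccl21a and Gm12238 have near-identical copies between which reads can be split, so their values are uncertain, and summed with its copy Amd1 stood at 83.1 and 79.96 FPKM.

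**Figure D3:**
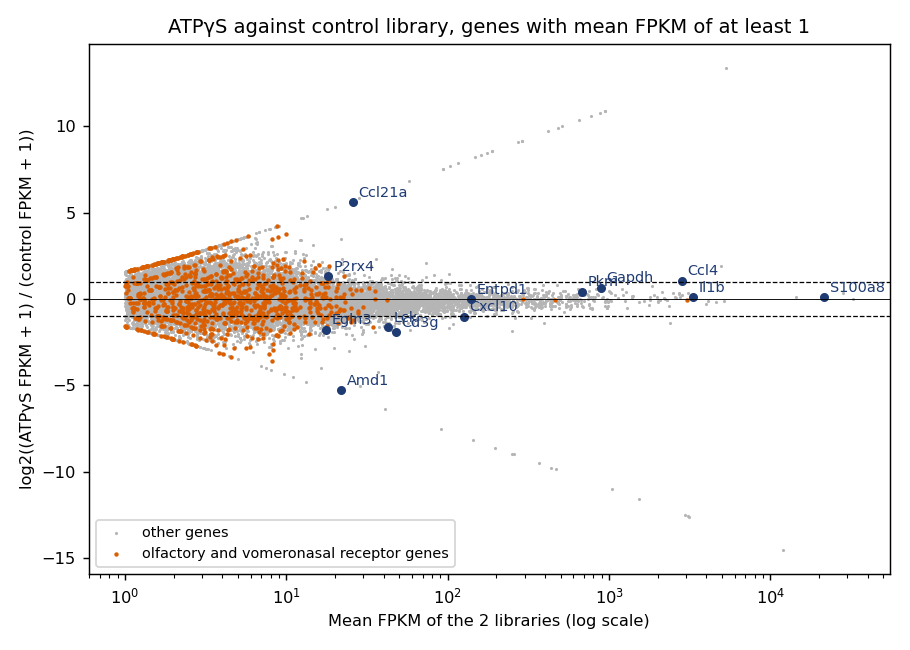
Log2 ratio of the ATPγS to the control library against mean FPKM (log axis) for the 18311 genes with a mean of at least 1, with olfactory and vomeronasal receptor genes in orange, some genes discussed here in blue and dashed lines at 2-fold. Points on the outer diagonals are genes listed at or near 0 in 1 library. The share of genes past 2-fold falls with level, from 32.1% of all genes at a mean of 1 to 5 to 7.30% at 20 or more.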

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

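The minimum of a mean FPKM of 20, rescaling together with a minimum, and the random lists matched on length or GC content were chosen after seeing the data. Leaving out the void alternative on repeated symbols, 10 of the 24 counts under alternatives stayed within 1.5 times. The genes at least 2-fold higher and lower numbered 561 and 461 with a pseudocount of 5, 740 and 894 at a mean FPKM of at least 5, and 80 and 174 at a mean of at least 20, where fewer genes enter. Rescaled to a median of 0 they numbered 2912 and 1499, with 916 and 689 at a mean of at least 5 and 110 and 116 at a mean of at least 20, and rescaled to the same sum 2673 and 1673. They numbered 4408 and 3782 at a 1.5-fold threshold and 1154 and 611 at a 3-fold threshold. Of 438 list values under alternatives, 426 kept their side of the percentile limits, 7 came inside them, 5 went outside, and 0 of those that stood apart turned direction. The ectonucleotidase median came inside at a mean FPKM of at least 5 (0.21) and against lists matched on GC content (0.52). That of the immediate early genes came inside as a mean (0.14), against unmatched lists (0.16) and matched on GC content (0.16). The T and NK list came inside with a pseudocount of 5 (-0.23) and the B cell list as a mean (-0.40). The cause was not tested. The macrophage and dendritic cell list went outside with a pseudocount of 5 (0.19) and at a mean FPKM of at least 5 (0.24) or 20 (0.23). The erythroid and platelet list did so when matched on length or GC content (1.18), but that check is void because only 5 of its 7 members have these values. The glycolysis, TCA cycle, oxidative phosphorylation and receptor lists stayed inside under every alternative that gave a value. At a mean FPKM of at least 20 the receptor and ectonucleotidase lists had too few members for a value. Of 892 values of named genes under alternatives, 39 no longer reached 2-fold, 32 of them with a pseudocount of 5, and 15 newly did. With 1 library per group no library could be left out. No paired analysis was possible because each group has 1 library. The depth of 2134000 and 2849000 fragments limits the low genes, whose values lie within the background of the receptor genes.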

Other observations

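The tests of gene copies, background spread, counting error and other cell types, the acinar list and the genes at a mean FPKM of at least 50 were chosen only after the result was seen. The second T and NK cell list was written after the result of the first such list, but before the values of its own genes were looked at. Of 1561 genes with a mean FPKM of at least 50, a level that 3 receptor genes reached, 34 were at least 2-fold higher in the ATPγS library and 45 at least 2-fold lower. Among the higher, Inhba, which encodes the activin A subunit, stood at 55.0 and 149.5 FPKM in control and ATPγS, Procr, of the endothelial protein C receptor, at 42.1 and 104.5 FPKM, and, below 2-fold, Hilpda, of a lipid droplet protein, at 67.6 and 129 FPKM. Below 2-fold, Hcar2, of the niacin and hydroxybutyrate receptor, stood at 1380.5 and 2298 FPKM and the neutrophil attractant gene Cxcl2 at 959 and 1452 FPKM. Lower in the ATPγS library were AW112010 (388 and 109 FPKM), an interferon-inducible transcript, and Ms4a4b (155 and 48.3 FPKM), Dgka (73.2 and 27.1 FPKM) and Cd69 (91.4 and 40.8 FPKM), genes that lymphocytes express. Also lower were Ndufv3 and Ndufb6 of respiratory complex I (90.6 and 25.9, 103 and 39.8 FPKM) and Mpc1 of the mitochondrial pyruvate carrier (96.1 and 41.4 FPKM). The fixed lists hold none of these 3 genes, and the oxidative phosphorylation list of 56 genes did not stand apart (median -0.19, percentile 13.4).

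Digestive enzyme genes of the exocrine pancreas were present in both libraries. The trypsinogen genes Prss2 (678 and 483 FPKM) and Try4 (354 and 168 FPKM), the elastase gene Cela2a (636 and 478 FPKM), the colipase gene Clps (613 and 466 FPKM), the lipase gene Pnlip (270 and 171 FPKM) and the carboxypeptidase gene Cpb1 (139 and 66.0 FPKM) were among them. Of 24 measured acinar genes, 23 had a log2 ratio below 0, 3 were at least 2-fold lower and 1, Try10, was at least 2-fold higher (1.61 and 10.02 FPKM), with a median of -0.40. These genes were chosen after values of some of them were seen, so no percentile of the median is given. The class Ib histocompatibility genes H2-Q6 (70.8 and 2.82 FPKM) and H2-Q8 (27.2 and 120.0 FPKM) differed in opposite directions, whereas H2-Q7 (24.6 and 25.5 FPKM) and H2-Q9 (53.5 and 50.2 FPKM) hardly differed. Gm1987 (56.7 and 0.783 FPKM) and Ccl21a (0.0950 and 51.8 FPKM) were likewise opposite, with sums of 56.8 and 52.6 FPKM, so reads assigned to either gene are not excluded as the cause.

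The 24 genes with the largest ratios, such as Gstp2 and Amd1, were examined for reads shared between near-identical gene copies, which a counting program can assign to either copy. Of the 21 genes that could be searched, 15 had no such copy among GENCODE M21 transcripts, among them Svs4, Cd5, Klrd1 and H2-Q6. Of the 5 with a copy in the tables, 4 fell below 2-fold once the values were summed over the copies, as in Gstp2 with Gstp1 (49.2 and 72.7 FPKM) and Apoo-ps with Apoo (31.7 and 46.6 FPKM), while Ccl21a was as far apart after summing. An abundant copy pulls the ratio of the sum towards its own whether or not reads were shared. The sums alone therefore cannot decide for these 4 genes. Amd2, the copy of Amd1, differed in the opposite direction (39.4 and 79.8 FPKM), so shared reads may account for the difference of Amd1. Gstp1 hardly differed (49.2 and 48.1 FPKM), so for Gstp2 the question stays open, as it does for Apoo-ps and Gm5643. For the 15 genes without a copy the question stays open because 1036 symbols of the tables, such as H2-Q8, have no entry in GENCODE M21. H2-Q6 summed with H2-Q8 stood at 98.0 and 123 FPKM. The question also stays open for Gm12238, whose copy is not in the tables, for Ccl21a, and for Defa4, Gm1987 and Cypt7, which were not searched. No biological explanation was tested.

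Genes with at least a 2-fold difference at a mean FPKM of 1 to 5 were set against the olfactory and vomeronasal receptor genes, of which 49.6% differed by as much, against 30.7% of other genes. Counting error of independent reads is argued against as the whole cause, since the squared Pearson residuals of 456 receptor genes averaged 4.27 (bootstrap interval 3.90 to 4.66), where independent reads give 1. A spread of background reads over genes, wider than counting error, may account for some differences at this level. The sets were matched on FPKM and not on reads, however. These 456 receptor genes averaged 12.4 reads over both libraries. Longer genes hold more reads at the same FPKM, as Nos2 did (about 7 and 71 reads). The share of receptor genes is therefore no fair measure for such genes. At a mean FPKM of at least 20, 19.4% of 36 receptor genes (interval 8.19 to 36.0) and 7.17% of 3444 other genes differed by as much. The bound first set for this level, a share of other genes outside that interval, was wrong because a lower share excludes nothing, so background and an effect of ATPγS both stay open there, as they do at a mean of 5 to 20, the level of P2rx4, where 37.4% of receptor genes and 20.6% of others differed by as much.

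Of the 18 T and NK cell markers, 11 had a log2 ratio below 0, Cd3g and Lck among them, and 7 above (10 and 8 after rescaling to a median of 0). The list's median of -0.44 came inside the limits with a pseudocount of 5. A second list of 38 such genes, none of which (0) is in another list, had a median of -0.68, below all 10000 matched random lists. Of its members, 29 were lower in the ATPγS library and 9 higher, with 8 at least 2-fold lower and 1, Xcl1, at least 2-fold higher (5.03 and 12.2 FPKM). Its most abundant members were Ltb (660.5 and 393 FPKM), which B cells also express, and Ccr7 (167 and 181 FPKM), which dendritic cells also express and which hardly differed. An equally lower share of all cells other than neutrophils is argued against in part, since the median of the epithelial and stromal list lay 0.63 above that of the second list (percentile 99.85 of differences between matched random lists), as did those of the monocyte (0.62, percentile 99.65) and macrophage and dendritic cell lists (0.86, percentile 99.99). The B cell (0.10, percentile 68.7) and eosinophil, basophil and mast cell (0.40, percentile 90.5) lists did not part from it in this way. Only 6 of 17 epithelial and stromal genes reached a mean FPKM of 20. Receptor genes at a mean of at least 1 had a median of 0.04, so background may hold that list near 0. Its stromal genes Dcn (605 and 587 FPKM) and Col3a1 (227 and 241 FPKM) hardly differed. Of its epithelial genes, Krt19 (50.8 and 31.3 FPKM) and Cdh1 were lower and the low Vil1 and Muc2 higher, so its median does not speak for epithelial cells. A lower share of some other cell types along with T and NK cells is therefore not excluded. The median of the acinar list lay 0.27 above that of the second list. Its genes were chosen after values of some of them were seen, so no percentile is given, and a lower share of acinar cells is not excluded either. Fewer T and NK cells in the ATPγS library, cells that the Gr-1+ CD11b+ sort would mostly remove, may account for the pattern. However, Gzma (45.8 and 66.1 FPKM) and, chosen after its values were seen, Gzmb (30.4 and 35.6 FPKM) were higher. An effect of ATPγS on the transcripts of T and NK cells also stays open because each condition is 1 library.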
